A study of Mus musculus with 8 samples.

How the data were processed

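The data are expression profiles of splenic CD8 T cells of C57BL/6 mice on 8 one-colour Affymetrix mouse genome arrays, 2 in each of 4 groups. Per the labels' protocols, T cells were positively selected with magnetic beads, cultured for 18 h with bone-marrow-derived dendritic cells at 10 T cells per dendritic cell, freed of dendritic cells through CD11c, and 100 ng of total RNA was turned into biotin-labelled cRNA. The antigen receptor of the T cells is not given in the sources used here. Groups were taken from the sample titles: wild-type cells with non-pulsed dendritic cells, and wild-type, PKCθ knockout and p50 cRel double knockout cells with dendritic cells pulsed with the ovalbumin peptide N4. An array whose title has no replicate number was taken as number 1 and the other of its group as number 2.

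The deposited values are intensity values, 1 signal per probe set on a linear scale, made with GCOS 1.4 and MAS5 per the submitters' processing notes. MAS5 summarises the perfect match and mismatch probes of a probe set. In the values themselves every array had a 2% trimmed mean of 500, the mark of global scaling, and the arrays were not quantile normalized. Detection calls were not used here. The table held 45101 probe sets, of which 64 were controls and were left out. Genes were named through the platform annotation that came with the value table: 34945 probe sets had 1 gene symbol, 932 had several and were not named, and 9160 were not in that table and stay unnamed here. Symbols were updated by Entrez identifier in RefSeq genes of assembly GRCm38.p6 for 34741 probe sets. That table was used for names and for which genes neighbour each other only. Nfkb1 is not reported here, since no probe set was named for it.

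Values were transformed as log2(signal + 16). Probe sets whose mean over the 8 arrays was under the 40th percentile (5.38 on the log2 scale) were left out, which kept 27022. Of the probe sets of 1 gene the one with the highest mean was used, which gave 12520 genes. All 8 arrays entered 1 linear model with a coefficient per group, fitted with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a mean-variance trend, 4 residual degrees of freedom). Differences with a Benjamini-Hochberg adjusted p under 0.05 over all genes were counted as changed. The comparisons were WT N4 with WT non-pulsed, each knockout with WT N4, the double knockout with the PKCθ knockout, and each knockout with WT non-pulsed. Arrays differed little in RNA quality measures: the 3' to 5' signal ratio of the Gapdh controls lay between 0.778 and 0.861 and that of actin between 1.03 and 1.20. Pearson's r between the 2 arrays of a group, across genes, lay between 0.977 and 0.987.

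The genes to name were fixed by a rule before the data were examined: Prkcq, Nfkb1 and Rel, in each of the 4 comparisons other than those of knockouts with WT non-pulsed the 10 largest rises and 10 largest falls among changed genes whose groups of arrays do not overlap (where fewer passed, those that passed and then the lowest p-values, up to 5 each way, said not to pass), up to 4 members of each list with the lowest p, and Il2ra, Ifng, Gzmb, Il2, Myc, Cd69 and Il7r, among a few fixed genes of which not all are reported here. Gene models without a name were left out. All changed genes had groups that do not overlap. Chance gives this for 33.3% of unselected genes with 2 arrays against 2, but passing the test nearly requires it, so it adds no support. A few genes outside the rule are named with the block results, the neighbourhood test and the gene families of the closing section, and were chosen after their values were seen. Of the genes named as changed, 1 in each of 3 comparisons had a further probe set that moved the opposite way (Acaca, Spry2 and Utf1).

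Fixed at the same time were 22 gene lists with 494 genes, of which 422 were measured. They cover activation, cytokines, cytotoxic granules, NF-kB, cell cycle, Myc and ribosome biogenesis, glycolysis, amino acid transport, cholesterol and fatty acid synthesis, naive and quiescence genes, effector transcription factors, inhibitory receptors, apoptosis, interferon-stimulated genes, TCR signalling, markers of dendritic cells and macrophages, B cells, CD4 T cells, NK cells, erythroid cells and neutrophils, and sex-linked genes. They were tested with limma's camera with a preset correlation of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated from the arrays and with fry. The estimated correlation rests on 4 residual degrees of freedom, and the simulated lists were not tested with it. Members past the test were counted over all genes and adjusted over the list alone.

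The share of the wild-type response kept is the median, over genes changed at least 2-fold in WT N4 cells, of a knockout's change from WT non-pulsed cells divided by that of WT N4 cells. For the correlation of the knockout effects, 100 simulations drew 2 unchanged groups and a shared control group as independent noise with the fitted spread. The replicate numbers were checked for pairing: the deviations of same-numbered arrays from their group means correlated across genes with r between 0.255 and 0.579 in all 6 pairs of groups, so the numbers were taken to pair the arrays, and a fit with the number as a block was read beside the main one. The labels do not say what a number shares. WT N4 and PKCθ knockout arrays correlated best with each other within a number, at 0.990 and 0.984, and the first 3 principal components held 72.1%, 10.7% and 6.22% of the variance.

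The steps were tested on simulated data: 200 of 12520 genes were changed in a simulated comparison of the double knockout with WT N4, 5 times per size. Of 4-fold changes 90.3% were recovered, with 7.00% false among the calls, and of 2-fold changes 38.2%, with 5.91% false. The sign was wrong in 0 calls, and camera called the list that was moved and 0 of 20 others. The simulated genes were independent and had no replicate effect, so these rates need not hold for correlated genes. Settings chosen at that time as alternatives were pseudocounts of 1 and 64, quantile normalization, median centring, no filter and a 60th percentile filter, the mean of a gene's probe sets, a fit of the 4 arrays compared, no mean-variance trend, array weights, the replicate block, each array left out in turn, and for the kept share genes chosen on 1 replicate number and measured on the other. Added after seeing the data were fits of the 6 N4 arrays, the mean B cell marker level as a covariate (and, for the genes higher in the double knockout, the dendritic cell and macrophage level and the neutrophil level in turn), counts without genes of the X and Y chromosomes, a count without marker genes and genes that followed the B cell markers at r over 0.9, and median centring for the lists.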

Results

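CD8 T cells, the lymphocytes that kill infected cells, were taken from mouse spleens with magnetic beads and cultured for 18 h with dendritic cells grown from bone marrow, at 10 T cells per dendritic cell. The dendritic cells carried no added peptide (non-pulsed) or were loaded with the ovalbumin peptide N4. Wild-type T cells met either kind of dendritic cell. T cells lacking PKCθ, a kinase that carries the T cell receptor signal to the transcription factor NF-kB, and T cells lacking the NF-kB subunits p50 and cRel met N4-loaded dendritic cells only. Dendritic cells were then depleted through their surface protein CD11c, and the RNA of each culture was read on 1 Affymetrix mouse array. Each of the 4 groups (WT non-pulsed, WT N4, PKCθ KO N4 and p50 cRel DKO N4) had 2 arrays. The median signal per array lay between 33.6 and 70.3 on arrays that all had a 2% trimmed mean of 500. The number of arrays limits the precision, and the labels do not say whether the 2 arrays of a group came from separate cultures or animals. The p-values therefore measure only the spread between these samples, which may be technical in some groups. The 2 WT non-pulsed arrays differed widely in Xist (SD 4.09), as described below, so they were not repeats of the same RNA. Levels and changes are on the scale of log2(signal + 16), which understates the changes of dim genes.

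The targeted genes were read first. Rel, which encodes cRel, lay at 9.67 ± 0.21 (SD, n = 2) in WT N4 cells and at 6.05 ± 0.19 in the double knockout. It fell by 3.62 (SE 0.26, limma adjusted p = 0.000984). Prkcq, which encodes PKCθ, lay at 11.54 ± 0.28 in WT N4 cells and at 10.88 ± 0.18 in PKCθ KO cells, a difference of -0.66 (SE 0.21, limma adjusted p = 1.00) that was -0.73 and -0.60 within replicate numbers 1 and 2. Against WT non-pulsed cells Prkcq was lower in PKCθ KO cells and passed (-0.83, limma adjusted p = 0.0128), a comparison in which peptide differs too. Where the Prkcq probe lies relative to the deleted part is not given in the sources used here, so its signal does not check that label. Nfkb1, which encodes p50, was not analysed here. Peptide itself moved neither gene past the test in wild-type cells, where Rel differed by -0.29 and Prkcq by -0.17 between WT N4 and WT non-pulsed.

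Sex-linked transcripts separated the genotypes. Eif2s3y, a Y chromosome gene, lay between 10.65 and 11.20 on the 4 wild-type arrays and between 5.42 and 6.73 on the 4 knockout arrays. Kdm5d and Uty, also on the Y chromosome, had the same pattern. Xist, which is transcribed from the inactive X chromosome, lay between 12.27 and 12.57 on the knockout arrays and at 5.18 and 6.65 on the WT N4 arrays. The WT non-pulsed arrays read 6.05 for Xist in replicate 1 and 11.84 in replicate 2. Every comparison of a knockout with wild-type cells is therefore also a comparison of arrays with different sex-linked transcripts. The wild-type comparison is not free of this: Xist in WT N4 differed from WT non-pulsed by -0.87 within replicate number 1 and -5.18 within number 2.

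In the wild-type cultures, N4-loaded dendritic cells were followed by higher genes of growth and division and higher single genes of cytokines and cytotoxic granules. Genes of resting T cells were lower. Markers of other cells fell as well, as described below, so part of these changes may reflect which cells the cultures held. Ifng, the main cytokine of effector CD8 cells, rose from 6.69 ± 1.56 (SD, n = 2) to 12.95 ± 0.70, by 6.26 (SE 0.64, limma adjusted p = 0.00016). Gzmb, the granule protease granzyme B, rose from 8.66 ± 1.74 to 14.01 ± 0.15, by 5.35 (SE 0.62). Il2, the T cell growth factor, rose by 4.19 (SE 0.30) and Il2ra, its receptor chain, by 3.81 (SE 0.27). Klf2, a transcription factor that keeps naive T cells quiescent and recirculating, fell by 5.55 (SE 0.22) and the survival receptor Il7r fell too (-3.29, SE 0.17). In all, 5101 of 12520 genes passed limma at a Benjamini-Hochberg adjusted p under 0.05, 2159 higher and 2942 lower with N4. Of these, 806 rose and 2022 fell at least 2-fold.

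The 10 largest rises were those of Crabp2, a retinoic acid binding protein (7.02, SE 0.31), the cytokine Il21 (6.59, SE 0.55), Ifng, the haematopoietic cytokine Il3 (6.03, SE 0.29), Gzmb, Adh4 (4.95), the inhibitory receptor Lag3 (4.52), Il17a (4.46, SE 1.13), the fatty acid ligase Acsl6 (4.37) and Gpr25 (4.32). Il17a rested on unequal controls: it lay at 8.53 ± 3.23 in WT non-pulsed cells and at 12.98 ± 0.44 in WT N4 cells. Controls were unequal for Ifng and Gzmb too. Within replicate numbers 1 and 2 Ifng rose by 7.86 and 4.66, and Gzmb by 6.68 and 4.01. The 10 largest falls were those of S100a9 (-6.93), Cd7 (-6.59), S100a4 (-6.53), the interferon-induced gene Ifit1bl1 (-6.34), the chemokine receptor Ccr9 (-6.23), Chil3 (-6.14), S100a8 (-5.58), Klf2, Sirpb1a (-5.53) and the B cell gene Ms4a1 (-5.48). Of the remaining fixed genes, Myc rose by 0.72 (limma adjusted p = 0.00504) and the early activation marker Cd69 by 0.65 (limma adjusted p = 0.0284).

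Markers of cells other than CD8 T cells fell with N4. All 17 measured B cell markers fell (median -4.37), among them Ms4a1, Fcmr (-5.11) and Cd22 (-4.31). Of 36 dendritic cell and macrophage markers 34 fell and 2 did not pass (median -3.81), with Csf1r at -4.76 and Mmp12 at -4.65, and all 10 neutrophil markers fell (median -4.19), with S100a9, S100a8 and Mmp8 (-5.29) leading. Adjusted over the list alone, 17, 34 and 10 passed. The 3 lists went down by limma's camera with its preset correlation. With an estimated correlation none did: adjusted p = 0.302 for B cells, adjusted p = 0.282 for dendritic cells and macrophages and adjusted p = 0.282 for neutrophils. Of 6 markers of CD4 T cells Cd40lg rose (1.56) and St8sia6 (-4.92), Gata3 (-2.21) and Zbtb7b (-1.90) fell. Of 5 NK and innate lymphocyte markers Cd160 rose (2.21) and Tyrobp (-5.32) and Fcer1g (-4.20), which myeloid cells also express, fell. Of 4 erythroid markers Car2 (-3.21) and Hbb-b2 (-1.59) fell. Those lists did not pass camera, nor did the 4 sex-linked genes, of which 0 passed limma.

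**Figure D1:**
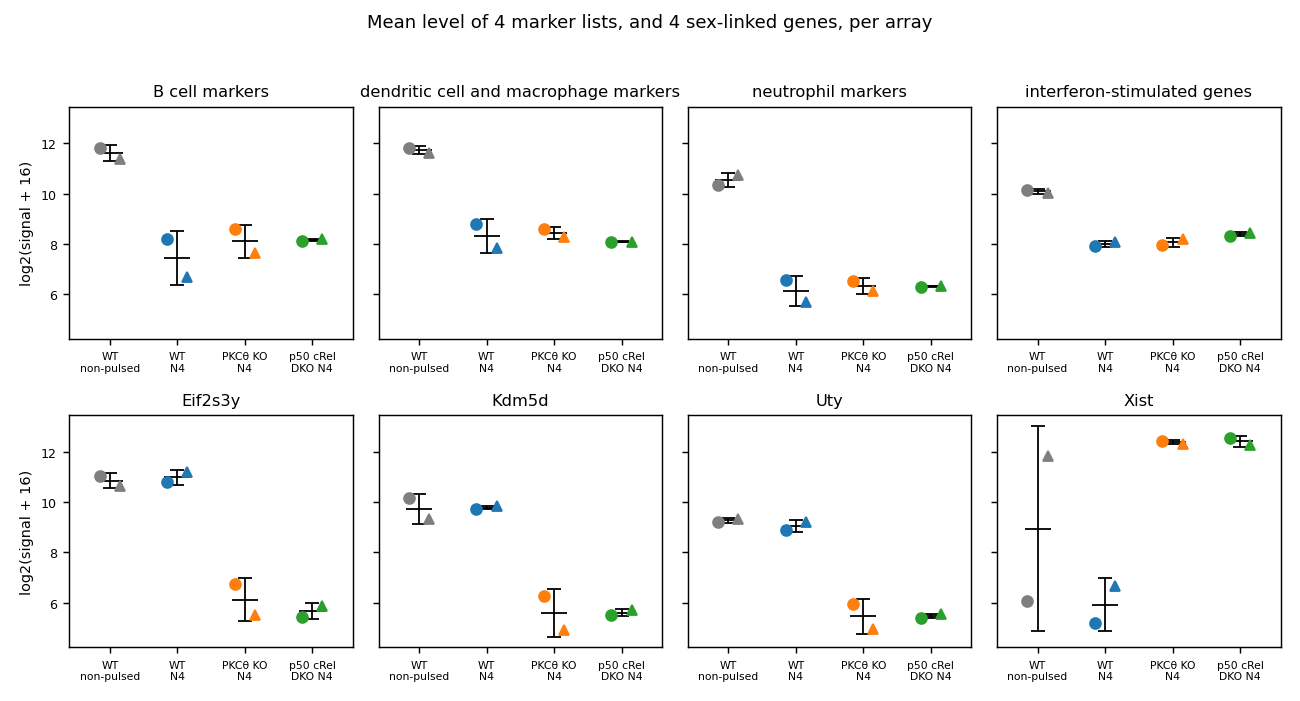
Level of other cells' markers and of sex-linked genes on each array. The upper panels plot the mean log2(signal + 16) of the measured genes of 4 lists and the lower panels that of 4 single genes; circles are arrays of replicate number 1, triangles those of number 2, and the bars give the group mean ± SD (n = 2). The B cell, dendritic cell and neutrophil markers of the WT non-pulsed arrays lie above those of every N4 array, and Eif2s3y, Kdm5d and Uty are lower on the knockout arrays than on the wild-type ones.

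Genes of division and growth rose together. Of 36 cell cycle genes 26 rose, 1 fell and 9 did not pass, with the replication genes Ccne2 (2.48), Cdc6 (2.24), Cdc45 (2.16) and Gins1 (1.92) at the lowest p; 30 passed adjusted over the list alone (adjusted p = 0.282 with an estimated correlation). Of 25 Myc and ribosome biogenesis genes 21 rose, led by Nolc1 (1.49), and 23 passed adjusted over the list alone (adjusted p = 0.282 with an estimated correlation). Glycolysis genes rose in 10 of 16 cases, with hexokinase Hk2 at 1.59 and the lactate transporter Slc16a1 at 1.16; 10 passed adjusted over the list alone (adjusted p = 0.302 with an estimated correlation). Among 18 amino acid transport and ATF4 target genes 11 rose, including Psat1 (1.64), Mthfd2 (1.38) and Slc7a5 (1.30), and 2 fell; 15 passed adjusted over the list alone (adjusted p = 0.282 with an estimated correlation). Of 22 cholesterol and fatty acid synthesis genes 8 rose, including Stard4 (1.44), Lss (1.27) and Acaca (1.08, with another probe set moving the opposite way), and 1 fell; 11 passed adjusted over the list alone (adjusted p = 0.387 with an estimated correlation).

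Effector genes moved in both directions. Of 17 activation markers 11 rose, including Il12rb2 (4.13), Il2ra and Il12rb1 (3.44), and 3 fell, including Tnfrsf1b (-2.16); 16 passed adjusted over the list alone (adjusted p = 0.302 with an estimated correlation). Of 16 cytotoxic granule genes 8 rose, including Gzmb, Prf1 (perforin, 2.54, and 0.57 in its other probe set), Nkg7 (1.78) and Serpinb9 (1.68), and 2 fell. Adjusted over the list alone 10 passed (adjusted p = 0.387 with an estimated correlation). Of 28 effector transcription factors 9 rose, including Nr4a2 (4.16), Tbx21 (2.61) and Nr4a3 (2.29), and 6 fell, including Egr3 (-2.44); 15 passed adjusted over the list alone (adjusted p = 0.282 with an estimated correlation). Camera called these 3 lists higher, and the cytotoxic and transcription factor calls were lost when the arrays were scaled by quantiles (adjusted p = 0.12 and adjusted p = 0.251) or by their medians (adjusted p = 0.124 and adjusted p = 0.131). Of 21 cytokines and chemokines 7 rose, including Il3, Il2 and Lif (4.13), and 5 fell, including lymphotoxin beta, Ltb (-3.24); 13 passed adjusted over the list alone, and camera did not call the list. Of 22 inhibitory receptors and signalling inhibitors 8 rose, including Lag3, Spry1 (4.04) and Ctla4 (2.78), and 5 fell, including Dgka (-1.47); 14 passed adjusted over the list alone, the median was -0.10 and the mean 0.61, and camera did not call the list. Of 24 TCR signalling genes 7 rose, including Cd5 (2.90) and Cd6 (2.47), and 4 fell, including Fyb (-2.64). Of 22 apoptosis and survival genes 4 rose, including Fasl (2.25), and 6 fell, including Bbc3 (-1.49). Adjusted over the list alone, 11 and 10 passed, and neither list passed camera; the apoptosis median was -0.11 and the mean 0.00.

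Genes of resting cells, interferon response and NF-kB fell alongside the B cell, dendritic cell and neutrophil markers. Of 29 naive and quiescence genes 17 fell, including Klf2, the PI3K inhibitor Pik3ip1 (-4.52), Il7r and Rasa3 (-2.28), and 1 rose; 18 passed adjusted over the list alone (adjusted p = 0.282 with an estimated correlation). Of 28 interferon-stimulated genes 24 fell (median -2.53), including Rtp4 (-4.60), Ifit3 (-3.78) and the RNA sensor Ifih1 (-3.41), and 1 rose; 25 passed adjusted over the list alone (adjusted p = 0.282 with an estimated correlation). Of 28 NF-kB subunits, feedback genes and targets 13 fell, including Slc2a6 (-2.65), Tnfrsf1b, Nfkbiz (-1.85) and Tnip1 (-1.39), and 1 rose; 20 passed adjusted over the list alone (adjusted p = 0.282 with an estimated correlation). In total camera called 14 of 22 lists with its preset correlation and 0 with an estimated one, and limma's fry, which asks whether the genes of a list move 1 way, called 20. With 4 residual degrees of freedom the estimated version could hardly call a list. It did not call even the B cell markers, all of which fell. Its missing calls, here and in the other comparisons, therefore decide nothing for or against a list.

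The balance of rises and falls depended on the scaling. The median change of all genes was -0.10 as deposited, 0.09 after quantile normalization and 0.32 after median centring, and the share of changed genes that were higher was 42.3%, 52.6% and 67.9%. Without the 1322 genes that are markers of B cells, dendritic cells or neutrophils or that followed the B cell markers across the arrays, as genes falling within T cells can too, 3564 genes passed, 2045 higher and 1519 lower.

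In PKCθ KO cells with N4, no immune gene passed the test against WT N4 cells. The 3 genes that passed were Eif2s3y (-4.88, limma adjusted p = 0.00948), Kdm5d (-4.18, limma adjusted p = 0.0294) and Uty (-3.60, limma adjusted p = 0.0176), the Y chromosome genes described above, and all 3 were lower. The largest difference of an immune gene among those named was that of Il2, at 9.33 ± 0.60 (SD, n = 2) against 11.55 ± 0.29, or -2.22 (SE 0.30), which was lower within both replicate numbers (-1.59 and -2.85) without passing (limma adjusted p = 0.135). Ifng (0.37), Gzmb (-0.10), Il2ra (-0.35), Myc (-0.03), Cd69 (-0.45) and Il7r (-0.65) did not pass either.

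After the Y chromosome genes, the lowest p-values among lower genes were those of Tent5a, a noncanonical poly(A) polymerase (-1.65, limma adjusted p = 0.0635), and Il2. With the replicate number as a block Tent5a passed (limma adjusted p = 0.0253), which made 4 genes. The lowest among higher genes, none past the test, were those of Cd8b1, a chain of the CD8 coreceptor (0.77), Atp8b4 (0.93), Rab4a (1.49), Efcab7 (1.41) and Slc9b2 (1.30), each at a limma adjusted p of 0.252. Cd8a differed by 0.78, Prf1 by 1.04, Klf2 by 1.28 and the costimulatory receptor Tnfrsf4 by -1.16. Rel differed by -0.37.

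Outside the sex-linked list, 0 members of the 22 lists passed limma over all genes. Adjusted over the list alone, some members of other lists passed. Among them were Il2 and Tnfrsf4, which were lower, and Cd8b1, Klf2 and Prf1, which were higher. Camera with its preset correlation called cholesterol and fatty acid synthesis lower (median -0.25, 0 of 22 genes past; adjusted p = 0.836 with an estimated correlation), B cell markers higher (median 0.56, 0 of 17 past; adjusted p = 0.836 with an estimated correlation) and the sex-linked list lower (3 of 4 fell; adjusted p = 0.409 with an estimated correlation). The cholesterol genes with the lowest p were Fads2 (-1.08), Scd2 (-0.67), Lss (-0.51) and Acaca (-0.38), and adjusted over the list alone 0 of them passed. Of the B cell markers, of which 0 passed adjusted over the list alone, Fcer2a differed by 1.20 and Ebf1 by 0.74. Fry called 1 list, the sex-linked one. Medians and means were near 0 with opposite signs for effector transcription factors (0.04 and -0.01), apoptosis (-0.04 and 0.02) and CD4 T cell markers (0.08 and -0.05). In all 371 genes had an unadjusted p under 0.05 in limma. The count of 3 fell to 0 when WT N4 replicate 2 was left out and to 1 when replicate 1 was, and it was 16 with the B cell marker level of each array as a covariate.

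Cultures of p50 cRel DKO cells held far less transcript of 3 cytokines than WT N4 cultures and more of 2 cytotoxic genes. Il2 fell from 11.55 ± 0.29 (SD, n = 2) to 7.42 ± 0.05, by 4.12 (SE 0.30, limma adjusted p = 0.000984), which put it near the 7.36 ± 0.34 of WT non-pulsed cells. Il3 fell by 4.58 (SE 0.29, limma adjusted p = 0.000984) and the chemokine Ccl9 by 2.17 (SE 0.29). Ccl9 also fell with N4 in wild-type cultures (-2.31), as markers of dendritic cells and macrophages did. Which cells its fall in the double knockout came from was not tested. Gzmc, granzyme C, rose from 6.84 ± 0.59 to 12.27 ± 0.11, by 5.43 (SE 0.47, limma adjusted p = 0.00253), and Prf1 by 2.28 (SE 0.20), though another probe set of Prf1 differed by only 0.10. Ifng (-1.12), Gzmb (0.33), Il2ra (-0.51), Myc (-0.07), Cd69 (-0.17), Il7r (0.47) and Prkcq (-0.05) did not pass.

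In all, 65 genes passed limma, 31 higher and 34 lower in the double knockout. The largest falls besides Il3, Il2, Rel and the Y chromosome genes Eif2s3y (-5.35), Kdm5d (-4.19) and Uty (-3.58) were those of Lad1 (-4.33), Pdlim4 (-2.72), the protease inhibitor Timp1 (-2.49) and Acsl6 (-2.47). The largest rises besides Gzmc and Prf1 were those of Ifit1bl1 (3.66), Cd7 (2.96), the glutathione transferases Gstt3 (2.95) and Gstt1 (2.20), Ifi213 (2.44), Tmem71 (2.35), the deubiquitinase Otud1 (2.21) and Ltb (2.20). Another probe set of Ifi213 differed by only 0.62. Xist differed by 6.50 without passing (limma adjusted p = 0.145). Of these 65 genes, 8 were lower among the 806 that N4 raised at least 2-fold in wild-type cells and 6 higher, while 19 were higher among the 2022 that N4 lowered and 7 lower. Both comparisons use the same WT N4 arrays, whose noise alone can give opposite signs, so these counts are no test of a weaker response.

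**Figure D2:**
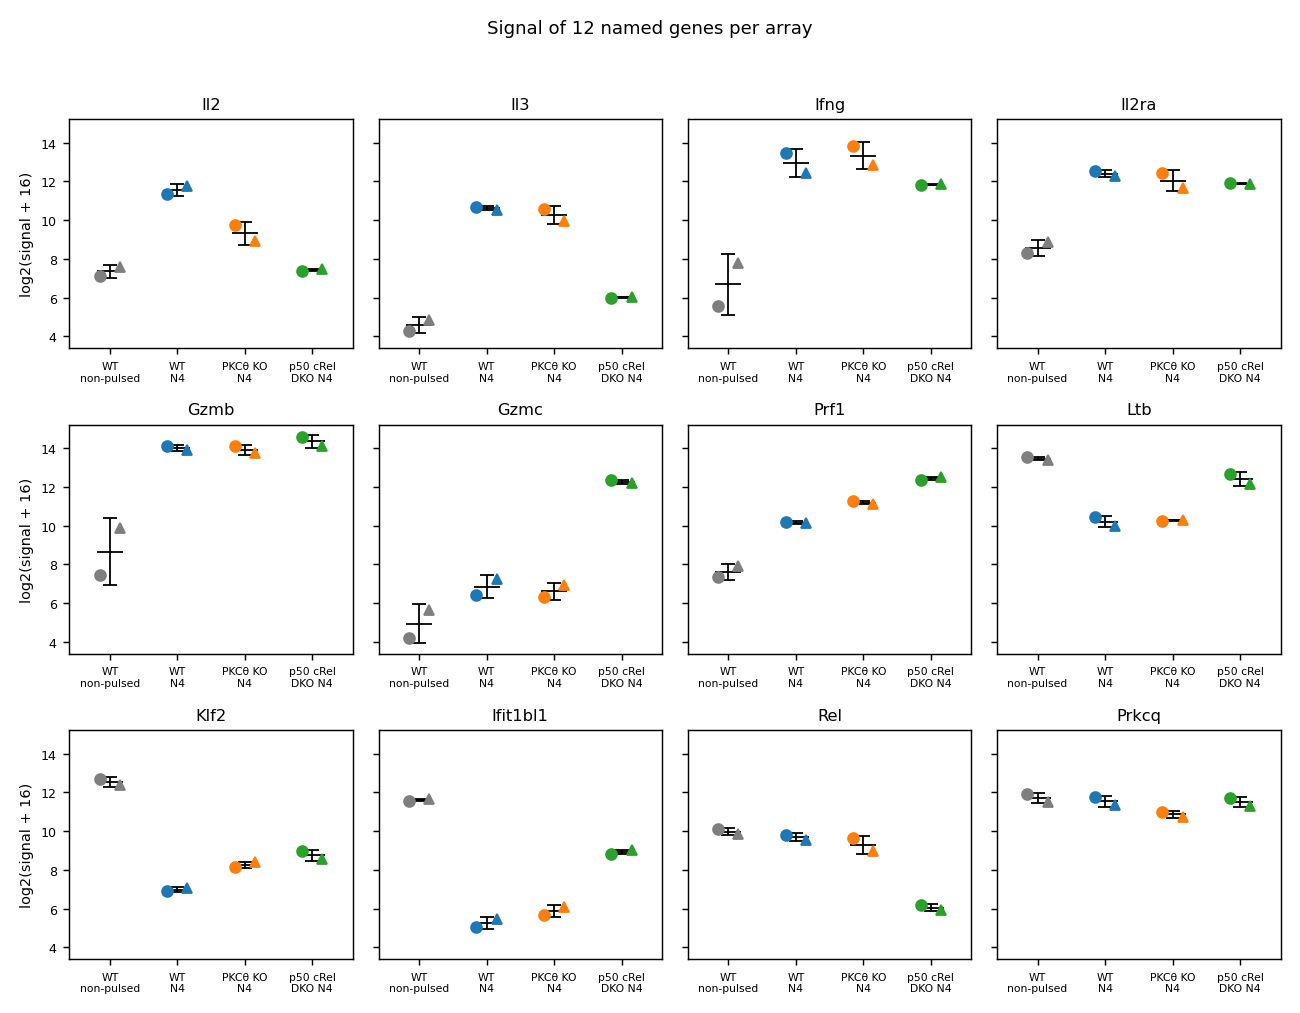
Signal of 12 named genes on each array. The vertical axes give log2(signal + 16); circles are arrays of replicate number 1, triangles those of number 2, and the bars give the group mean ± SD (n = 2). Il2 of the double knockout lies near the WT non-pulsed level, Il3 lies between that level and WT N4, Gzmc lies above every other group, and Ltb and Klf2 lie between WT N4 and WT non-pulsed.

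By list, cytokines and chemokines went lower: Il3, Il2 and Ccl9 fell, Ltb rose and 17 of 21 did not pass, and adjusted over the list alone 6 fell and 1 rose (adjusted p = 0.411 with an estimated correlation). Among 28 effector transcription factors Bhlhe40 (-1.26) and Stat5a (-0.91) fell and 0 rose, and adjusted over the list alone 3 fell and 2 rose, Egr3 (1.46) among the latter (adjusted p = 0.303 with an estimated correlation). Cytotoxic granule genes were called higher, with Gzmc and Prf1 rising and 14 of 16 not past; 4 rose and 3 fell adjusted over the list alone (adjusted p = 0.602 with an estimated correlation). Among 29 naive and quiescence genes Klf2 rose (1.77) and the rest did not pass, and 4 rose and 1 fell adjusted over the list alone (adjusted p = 0.392 with an estimated correlation). Of 28 interferon-stimulated genes Ifit3 (2.11) and Rtp4 (1.76) rose, and 2 passed adjusted over the list alone (adjusted p = 0.376 with an estimated correlation). Camera also called TCR signalling higher (median 0.28, 0 of 24 past; Rasgrp1 at 0.78 and Lcp2 at 0.76; adjusted p = 0.451 with an estimated correlation) and glycolysis lower (median -0.33, 0 of 16 past; Hk2 at -0.86; adjusted p = 0.602 with an estimated correlation). The glycolysis median was 0.05 within replicate number 1 and -0.55 within number 2.

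Camera with its preset correlation also called 3 lists of other cells' markers, B cells and NK cells higher and dendritic cells and macrophages lower, with 0 members past limma over all genes. B cell markers had a median of 0.62 (adjusted p = 0.625 with an estimated correlation), which was 0.04 within replicate number 1 and 1.60 within number 2. NK markers had a median of 0.89 (adjusted p = 0.376 with an estimated correlation) and dendritic cell and macrophage markers one of -0.21 (adjusted p = 0.602 with an estimated correlation), which was -0.76 within replicate number 1 and -0.03 within number 2. Of 28 NF-kB genes Rel alone passed over all genes, and adjusted over the list alone 5 fell, including Nfkbie (-0.82) and Gadd45b (-0.68), and 2 rose, including Relb (0.93). Of 22 inhibitory receptors and signalling inhibitors Spry2 rose (2.10), though another probe set of Spry2 moved the opposite way; camera called neither list. Cell cycle (0 of 36 past, median 0.04) and Myc and ribosome biogenesis (0 of 25 past, median -0.01) were not called. Camera called 11 lists with its preset correlation and 0 with an estimated one, and fry called 2, the NK and sex-linked ones; apoptosis had a median of -0.10 and a mean of 0.02, and 788 genes had an unadjusted p under 0.05 in limma.

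With the replicate number as a block 200 genes passed in the double knockout, 102 higher and 98 lower, including all 65. Among them were the thymocyte selection gene Themis (-1.69, limma adjusted p = 0.00454), Il12rb2 (-1.58), Hk2, Nfkbie (-0.82), Nr4a3 (-0.70), Gadd45b (-0.68), the NF-kB subunit Relb (0.93, limma adjusted p = 0.0165), Nrn1 (2.21), Egr3 (1.46), Dusp6 (1.39), Il6ra (1.37) and Xist, while the cytotoxic and NK lists lost their camera calls (adjusted p = 0.0704 and adjusted p = 0.0772). The count of 65 was 13 without double knockout replicate 2, 15 without its replicate 1, 30 without WT N4 replicate 2 and 35 without WT N4 replicate 1.

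Compared directly, the 2 knockouts differed in the same cytokine and granule genes. Il3 was lower in the double knockout than in PKCθ KO cells by a log2 difference of -4.24 (SE 0.29, limma adjusted p = 0.00255), Ccl9 by -3.15 (SE 0.29) and Il2 by -1.90 (SE 0.30, limma adjusted p = 0.0416). Gzmc was higher by 5.66 (SE 0.47, limma adjusted p = 0.00361), Ltb by 2.13 and Prf1 by 1.25 (0.21 in its other probe set). This comparison tests whether the effects of the knockouts differ, since both are read against the WT N4 arrays, and 54 genes passed it, 30 higher and 24 lower in the double knockout. Further large falls were those of Rel (-3.25), Mreg (-3.10), Mme (-2.47), Nid1 (-2.35), Acsl6 (-2.31), Mt2 (-2.26), Utf1 (-2.12, with another probe set moving the opposite way) and the chemokine receptor Cxcr5 (-2.07). Further large rises were those of Ifit1bl1 (3.03), Nrn1 (2.76), Cd7 (2.71), Igfbp7 (2.60), Gstt1 (2.39), Ifi213 (2.37, and 0.59 in its other probe set) and Ifit3 (2.12). Il7r was higher by 1.12 (limma adjusted p = 0.0339), Ifng differed by -1.49, Gzmb by 0.43, Il2ra by -0.16, Myc by -0.04 and Cd69 by 0.28 without passing.

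By list, cytokines and chemokines (Il3, Ccl9 and Il2 lower, Ltb higher, 17 of 21 not past) and effector transcription factors (Bhlhe40 lower at -1.07, Egr1 higher at 1.88, 26 of 28 not past) were called lower in the double knockout, and naive and quiescence genes (Il7r higher, 28 of 29 not past) and interferon-stimulated genes (Ifit3 and Rtp4 higher, 26 of 28 not past) were called higher. Adjusted over the list alone, 5, 5, 7 and 3 of them passed. Glycolysis (median -0.44, 0 of 16 past), amino acid transport and ATF4 targets (median -0.17, 0 of 18 past) and dendritic cell and macrophage markers (median -0.27, 0 of 36 past) were called lower, and 0, 1 and 1 passed adjusted over the list alone. These 7 calls were lost with an estimated correlation, each at adjusted p = 0.501 with an estimated correlation, and fry called 0 lists. Mean glycolysis levels of double knockout and PKCθ KO arrays were 12.03 and 12.10 within replicate number 1, and 11.90 and 12.74 within number 2. Those of amino acid transport and ATF4 targets were 10.89 and 10.96, and 10.81 and 11.31, so both differences lay mainly within number 2. In all 897 genes had an unadjusted p under 0.05 in limma. NF-kB genes, which camera did not call, had a median of 0.03 and a mean of -0.12, and of 6 CD4 T cell markers Izumo1r was higher (1.83). With the replicate number as a block 152 genes passed, 89 higher and 63 lower, and Prkcq, at 0.62, was among them (limma adjusted p = 0.0301, against 0.51 without the block). The count of 54 was 0 without double knockout replicate 1, 2 without its replicate 2, 13 without PKCθ KO replicate 2 and 34 without PKCθ KO replicate 1.

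Against WT non-pulsed cells, both knockouts still showed most of the difference between WT N4 and WT non-pulsed cells, in which the falling markers of other cells are included. Ifng was higher by 6.63 in PKCθ KO cells and by 5.14 in the double knockout, Gzmb by 5.25 and 5.68, Il2ra by 3.46 and 3.31 and Myc by 0.69 and 0.65, while Il7r was lower, at -3.93 and -2.82. Il2 rose by 1.96 in PKCθ KO cells (limma adjusted p = 0.00117) and differed by 0.06 in the double knockout (limma adjusted p = 0.896). Cd69, at 0.20 and 0.48, passed in neither, though in the double knockout it did with the replicate number as a block (limma adjusted p = 0.0484). Genotype and peptide both differ here, because knockout cells with non-pulsed dendritic cells were not analysed here, and 5078 and 4917 genes passed limma, 2067 and 2064 of them higher. Over the 806 genes that rose at least 2-fold in wild-type cells the median share of the change kept was 94.0% in PKCθ KO cells and 95.4% in the double knockout, and over the 2022 that fell it was 96.8% and 94.2%. Within replicate numbers 1 and 2 the shares of the raised genes were 95.8% and 92.1% in PKCθ KO cells and 93.8% and 96.7% in the double knockout.

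In these comparisons with WT non-pulsed cells, 28 of 36 cell cycle genes rose in PKCθ KO cells and 30 in the double knockout, 20 and 21 of 25 Myc and ribosome biogenesis genes rose, and 23 of 28 interferon-stimulated genes fell in each. All 17 B cell markers and all 10 neutrophil markers fell in each, with B cell medians of -3.60 and -3.74. Camera called 13 and 15 lists with its preset correlation and 0 with an estimated one (smallest adjusted p = 0.285 and adjusted p = 0.319 with an estimated correlation), and fry called 19 and 18. After quantile normalization the higher share of the changed genes went from 40.7% to 51.8% in PKCθ KO cells and from 42.0% to 52.3% in the double knockout, and after median centring it was 68.3% and 67.8%.

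Across genes, which are not independent replicates, the effects of the knockouts against WT N4 cells correlated with r = 0.403, and with r = 0.356 without genes of the X and Y chromosomes. Both effects use the same 2 WT N4 arrays. In 100 simulations unchanged groups set against a shared control group, all drawn as independent noise, gave r = 0.4997. Sharing a control group gives about that r when both groups are unchanged and the spreads are equal, and the pairing of arrays by replicate number was not simulated. The covariance was 0.0483 against a simulated 0.0458, or against 0.0276 when the spread was taken from the fit with the replicate number as a block. Part of any shared change may come from the shared controls, which are too few to split. The genes that passed in both were the Y chromosome genes Eif2s3y, Kdm5d and Uty, lower in both, which follow the sex-linked pattern; independent lists of 3 and 34 genes would share 0.00815, a number that leaves out the shared arrays, and 0 of the 31 genes higher in the double knockout passed in PKCθ KO cells.

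**Figure D3:**
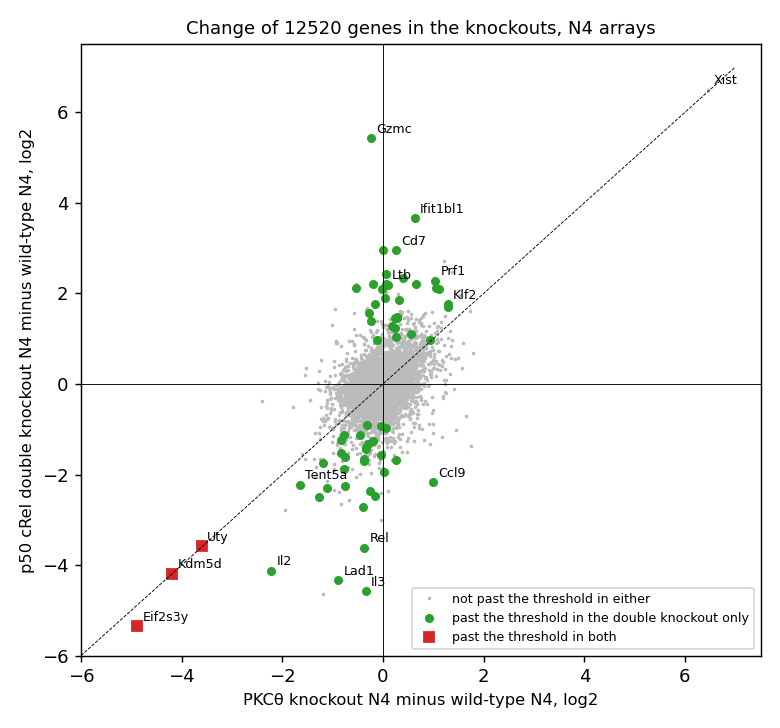
Change of each tested gene in PKCθ KO N4 cells (horizontal axis) and in p50 cRel DKO N4 cells (vertical axis), both as log2 differences from WT N4 cells (n = 2 arrays per group). Squares mark the 3 genes past the threshold in both comparisons, large dots those past it in the double knockout only, small dots the rest, and the dashed line marks equal changes. Il2 lies lower in both, while Il3 and Gzmc lie near 0 on the horizontal axis.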

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

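Of the 27022 probe sets tested, 3384 had no gene symbol in the annotation used here. Tested in the same limma fit, 542 of them differed between WT N4 and WT non-pulsed cells (127 higher and 415 lower with N4), 2 between PKCθ KO and WT N4 cells, 6 between the double knockout and WT N4 cells, and 4 between the double knockout and PKCθ KO cells. All of those 2, 6 and 4 were lower in the cells named first. Which genes they read was not examined, and counting them was decided after the gene results had been seen.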

How the results depend on the processing

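Calls in the comparison of WT N4 with WT non-pulsed cells, and of each knockout with WT non-pulsed cells, kept their total count within 1.5 times under the settings of transformation, scaling and filter, but scaling moved their balance: in WT N4 against WT non-pulsed 2159 were higher and 2942 lower, and after median centring 3661 and 1728. The small counts between N4 groups moved more. Of 166 calls of named genes, 2716 values under other settings kept 2471, weakened 245 and reversed 0, most often when a double knockout array was left out (45 without replicate 1 and 42 without replicate 2). The cause was not tested.

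PKCθ KO against WT N4, with 3 genes, had 1 with pseudocount 1, 1 after quantile normalization, 1 with no filter on low values, 0 with no mean-variance trend, 5 from only the 6 N4 arrays, 16 with the B cell marker level as a covariate and 0 without X and Y genes. With arrays left out in turn it had 0 to 3: 0 without WT N4 replicate 2, 1 without WT N4 replicate 1 and 3 without PKCθ KO replicate 1. The double knockout against WT N4, with 65, had 35 with no mean-variance trend, 200 with the replicate block, 136 with the B cell marker covariate, and 13 to 35 with arrays left out (13 without its replicate 2, 15 without its replicate 1, 30 without WT N4 replicate 2, 35 without WT N4 replicate 1). The double knockout against PKCθ KO, with 54, had 28 with no filter on low values, 98 from only the 4 arrays compared, 17 with no mean-variance trend, 152 with the replicate block, 175 with the B cell marker covariate, and 0 to 34 with arrays left out (0 without double knockout replicate 1, 2 without its replicate 2, 13 without PKCθ KO replicate 2, 34 without PKCθ KO replicate 1). The double knockout against WT non-pulsed had 3229 to 3746 genes with arrays left out, 3229 without its replicate 1 against 4917. WT N4 against WT non-pulsed had 3546 to 4258, and PKCθ KO against WT non-pulsed 3761 to 4132.

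The median share of the wild-type change kept in PKCθ KO cells was, for genes down, 94.6% after quantile normalization and 94.0% after median centring. For genes up it was 98.5% after median centring. In the double knockout it was 96.5% for genes down, with genes chosen on 1 replicate number. With arrays left out it lay between 87.8% and 97.4% (PKCθ KO, up), 94.3% and 98.7% (PKCθ KO, down), 89.0% and 96.1% (double knockout, up) and 91.2% and 95.3% (double knockout, down). The correlation of the knockout effects lay between 0.204 without PKCθ KO replicate 1 and 0.652 without WT N4 replicate 1. Camera with estimated correlation called 0 gene lists in WT N4 against WT non-pulsed, 0 in PKCθ KO against WT N4, 0 in the double knockout against WT N4, 0 in the double knockout against PKCθ KO, and 0 in either knockout against WT non-pulsed. Fry called 1 list in PKCθ KO against WT N4, 2 in the double knockout against WT N4 and 0 in the double knockout against PKCθ KO. PKCθ KO against WT N4 had 5 lists after quantile normalization and 5 after median centring, against 3.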

Other observations

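Families of genes outside the lists, chosen after the values were seen, moved in different directions in wild-type cells with N4. Of 76 mitochondrial ribosomal proteins 53 rose and 0 fell (median 0.63, 0.61 after quantile normalization and 1.05 after median centring). Of 50 genes whose symbols start with Rpl or Rps and a digit, 2 rose and 2 fell. Such symbols name cytosolic ribosomal proteins, but also S6 kinases (Rps6k), which were not taken out. Of 39 proteasome subunits 18 rose and 2 fell (median 0.40, 0.23 after quantile normalization and 0.82 after median centring), and of 30 heat shock proteins and chaperonins 14 rose (median 0.37, 0.33 and 0.79). Of 16 chemokine and S1P receptors, which steer lymphocytes between blood and tissue, 9 fell (median -1.55), including Ccr9 (-6.23), the egress receptor S1pr1 (-4.12) and Cxcr4 (-3.09), while Ccr1 (-3.11) is a receptor of myeloid cells. Camera called these families, without the Rpl and Rps genes, with its preset correlation (adjusted p = 0.00244 or lower) and none with an estimated one (adjusted p = 0.386 or higher with an estimated correlation).

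In the double knockout, killer lectin receptors, which NK cells and activated CD8 T cells carry, differed from WT N4 cells in 1 of 11 members: Klrc1 rose (2.12), while Klrd1 was at 1.502 (limma adjusted p = 0.0677) and Klrg2 at -0.91 without passing, and the median was 0.89 (adjusted p = 0.179 with an estimated correlation). In PKCθ KO cells their median was 0.34 (adjusted p = 0.668 with an estimated correlation). Of 27 chemokines Ccl9 alone fell, with a median of -0.39 (adjusted p = 0.179 with an estimated correlation).

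The tests of the share of other cells, of scaling, of sex, of other cells in the double knockout and of a weaker fall were chosen only after the result was seen; those of neighbouring genes and of the genes around Prkcq were written before their values were seen.

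Lower markers of other cells in WT N4 than in WT non-pulsed cultures are consistent with a smaller share of those cells in the stimulated cultures, though bead selection of T cells and depletion through CD11c were meant to remove them from every culture. Of 63 markers of B cells, dendritic cells, macrophages and neutrophils 96.8% fell and 0 rose, while of 6 CD3 and CD8 chain genes 0 fell and Cd8a (1.07) and Cd247 (0.67) rose, with a median of -0.01 among them. The wording that none of those chain genes falls replaced, once the values were known, one about their median, under which the result could not be told, and a fall of these markers within T cells was not tested. Scaling of the arrays did not account for it, since the median marker difference was still -3.45 after median centring.

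The changes of the double knockout have several candidate explanations besides the missing NF-kB subunits. Sex of the mice did not account for the whole change of 30 of the 61 genes outside the X and Y chromosomes. These also differed from PKCθ KO cells, whose arrays had the same sex-linked transcripts. The same held for 13 more with the replicate number as a block, and could not be told for the other 18. Part of a change may still go with sex. PKCθ KO cells showed a median of 2.84% of the double knockout change of the 30 genes, and 18.6% of that of the 13. For Il2, among the 30, they showed -2.22 against -4.12. More B cells, dendritic cells, macrophages or neutrophils were examined for the 31 higher genes only, with each marker level as a covariate. With each of the 3 levels 26 genes still passed. The other 5 hardly moved with the neutrophil level (Lpxn 0.97, SE 0.15, and 0.96, SE 0.16). They no longer passed in that fit, which called 69 genes, against 136 with the B cell level. The covariate rests on differences within groups of 2 arrays, so these fits alone cannot exclude such cells. The level of NK markers, which camera and fry called higher in the double knockout, was not used as a covariate. Of a pair of earlier tests, replaced after their results were seen, the looser had ruled such cells out for all 31. The stricter had 4 above the markers within both replicate numbers and left 27 open. Whether fewer of these cells lowered any of the 34 lower genes was not tested. Genomic segments of another strain may have contributed, since changed genes lay near each other more often than random genes (9 pairs against 1.49, one-sided permutation p = 1e-04, the smallest they can give), among them Il3, Acsl6 and Pdlim4, though neighbouring paralogs and co-regulated genes give the same, and near Rel or Nfkb1 there was 1 changed gene against 0.988 (one-sided permutation p = 0.632). Of the 30 genes higher than in PKCθ KO cells 16 were among those that fell with N4 in wild-type cells, against 4.85 expected (one-sided Fisher exact p = 3.02e-06), as a weaker fall would give, but 5 were among those that rose, against 1.93 (p = 0.0407), and of 24 lower genes 7 had risen, against 1.55 (p = 0.000587), and 7 had fallen, against 3.88 (p = 0.0794).

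Genes around Prkcq were examined for a segment of another strain next to the deletion, which could add differences to the PKCθ KO cells. The 75 tested genes around it did not differ from WT N4 cells more than other stretches of as many neighbouring genes did (one-sided exact rank p = 0.398 among all 11014 overlapping stretches). Around Nfkb1 the same exact rank p was 0.0282 in the double knockout against WT N4 and 0.0197 in PKCθ KO cells against WT N4, uncorrected for the 7 stretches examined. Both values use the same WT N4 arrays, so they are not separate evidence. Between the knockouts, without those arrays, the exact rank p was 0.0922. The Slc9b2 gene near Nfkb1 rose in the double knockout (1.71). Around Rel the exact rank p was 0.281 in the double knockout and 0.718 in PKCθ KO cells, and around Prkcq 0.207 in the double knockout. Since the PKCθ KO cells have no targeted Nfkb1, a segment linked to that allele cannot be the source of their value around Nfkb1.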
